A study of Mus musculus with 16 samples.

How the data were processed

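RNA sequencing of brain tissue from mice with a conditional deletion of Rai1 was analysed in 16 libraries. They fall into 8 groups of 2 replicates: cortex at 3 weeks, striatum at 3 weeks, striatum at 12 weeks and hypothalamus at 8 weeks, each with a group labelled wild type and a group labelled knockout. Per the labels' protocols, total RNA was extracted with Trizol from flash-frozen tissue. Per the labels' protocols, the Cre drivers were Nestin-Cre for cortex, Gad2-Cre for striatum and Vglut2-Cre for hypothalamus. Per the labels, the cortical and striatal mice were B6/FVB F1 and the hypothalamic mice B6/129 F1. Strain, region, driver and age therefore differ together between hypothalamus and the other regions. The part of Rai1 that was deleted is not given in the sources used here. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

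The authors deposited a table of RPKM values, which are reads scaled for gene length and library depth, for 24176 gene symbols, with no symbol listed more than once. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt 1.6 and TopHat2 were used with the mouse build mm9. The version of TopHat2, the read counter, its strand setting, the treatment of reads that match several places and the RPKM denominator are not given in the sources used here. Overlapping genes, antisense pairs and near-identical copies are therefore uncertain, and Ipw and A230057D06Rik lie in a region of overlapping transcripts. Gene types, lengths and neighbours were taken from GENCODE annotation of another mouse build, in which 23832 symbols were matched, and no coordinates are given.

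The depth was recovered from the RPKM step that 1 read makes in genes with a single exon. Libraries held 21708242 to 35635562 reads by this estimate. Between 71.6% and 79.6% of the 338 to 430 single-exon genes used per library gave whole reads within 0.05 read. RPKM summed to 82332 to 126722 per library. Listed genes took about 44.0% to 64.0% of the reads, so the denominator includes reads outside them. Approximate reads per gene were used for depth statements and added alternatives only. A floor of 3 reads was taken for a value of 0, and it covers counting error only.

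Values were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with a mean for each of the 8 groups fitted over all 16 libraries and a variance trend on expression. Genes with at least 1 RPKM in at least 2 libraries were kept, which left 12348 genes and 8 residual degrees of freedom. Log2 changes are on the log2(RPKM + 0.5) scale and understate changes of low genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Comparisons were the libraries labelled knockout against those labelled wild type in each of the 4 region and age sets, the mean of these 4 differences, the difference of the knockout effect between 12 and 3 weeks in striatum and between cortex and striatum at 3 weeks, and wild-type striatum at 12 against 3 weeks. Wild-type libraries are not shared between the 4 knockout comparisons. Overlaps of gene lists were tested with Fisher's exact test, two-sided.

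Before the data were examined, 39 gene lists were written, of pathways, receptor and channel families, adhesion molecules and cell type markers, and 37 had at least 3 tested genes. They were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. The alternatives were camera with an estimated correlation and fry. Counts of members adjusted over the list alone are given beside those over all genes tested. The rule for named genes was also fixed then. For each knockout comparison it took Rai1 and up to 12 called genes per direction by size of the log2 change, with at least 1 RPKM in the higher group and separated libraries. Where fewer than 5 were called in a direction, the genes of smallest p up to 5 were named as not passing. It also took up to 4 members of smallest p per list, up to 10 genes per direction for the mean and up to 8 for interactions and age, and the Cre-driver loci, sex-linked genes and genes beside Rai1 as checks.

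The fit was tested on simulated data for all 12348 genes, with 200 genes changed per draw and 5 draws per size. For the cortex comparison, 0.2% of genes changed by 0.5 on the log2 scale were recovered, 87.9% of those changed by 1 with 5.8% false calls, and 98.7% of those changed by 2. For the mean over 4 comparisons, 88.0% of genes changed by 0.5 were recovered, with 5.2% false calls. The simulated noise was independent between genes, with a single variance per gene for all sets and no shift of whole libraries. These rates therefore do not cover the shifts between libraries given below. Alternatives were other pseudocounts, filters, scalings and thresholds, a replicate block, fits of the compared groups alone, an untrended variance and leaving out each library. Averaging rows of a symbol was planned but changes nothing here, since each symbol has a single row. Figures were drawn with matplotlib 3.10.9.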

Results

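Gene expression was measured by RNA sequencing in cortex, striatum and hypothalamus of mice carrying a conditional deletion of Rai1, a gene for a nuclear chromatin-associated protein whose loss causes Smith-Magenis syndrome in people. Each of the 4 region and age sets held 2 libraries labelled wild type and 2 labelled knockout, with a depth of 21708242 to 35635562 reads by the estimate from RPKM steps. Replicate libraries correlated at Pearson r of 0.971 to 0.991 across genes, which are not independent replicates. All 16 libraries had Xist at or below 0.064 RPKM and the Y-linked gene Ddx3y at or above 3.31 RPKM. Values below are RPKM, as mean ± SD with n = 2, and adjusted p-values are from limma unless another test is named.

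Rai1 itself was measured first, as a check of the labels. In cortex at 3 weeks the libraries labelled wild type had Rai1 at 4.35 and 5.70 RPKM and those labelled knockout at 4.28 and 3.03, a log2 change of -0.42 (SE 0.17) that did not pass the test. In the other sets Rai1 was higher in the libraries labelled knockout. It went from 3.77 and 3.24 to 6.52 and 7.01 in striatum at 3 weeks (log2 change 0.86, SE 0.17, adjusted p = 0.222). In striatum at 12 weeks it went from 5.08 and 4.88 to 12.3 and 13.3 (1.28, SE 0.17, adjusted p = 0.0164). In hypothalamus it went from 3.68 and 3.99 to 8.46 and 6.52 (0.87, SE 0.17, adjusted p = 0.481). These directions go against the labels, so libraries are called here by their labels, and every direction below is of libraries labelled knockout against libraries labelled wild type. The table holds a value for the whole gene only, and the deleted part is not given, so reads from the rest of the gene cannot be separated. The call in striatum at 12 weeks was lost without any of its 4 libraries, with adjusted p-values of 0.0668 and 0.304 without wild-type replicates 1 and 2 and 0.123 and 0.31 without knockout replicates 1 and 2. Of 29 tested genes flanking Rai1, the mouse counterparts of the segment deleted in the syndrome, none passed in any of the 4 sets. The Cre-driver loci did not pass over all genes in single sets either. Gad2, for a GABA-synthesizing enzyme, was at 39.6 ± 5.49 and 22 ± 1.90 in striatum at 3 weeks and at 34.0 ± 5.81 and 23.9 ± 1.92 at 12 weeks. Slc17a6, for the vesicular glutamate transporter VGLUT2, was at 42.4 ± 0.0979 and 31.5 ± 0.743 in hypothalamus. Adjusted over the 3 driver loci alone, Gad2 was lower in striatum at 3 weeks (log2 change -0.83, adjusted p = 0.00141), Slc17a6 higher there (0.41, adjusted p = 0.00577) and lower in hypothalamus (-0.42, adjusted p = 0.00964), and Nes higher in cortex (0.51, adjusted p = 0.00572). Over all genes, Gad2 was lower in the mean of the 4 sets (-0.50, adjusted p = 0.0278).

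**Figure D1:**
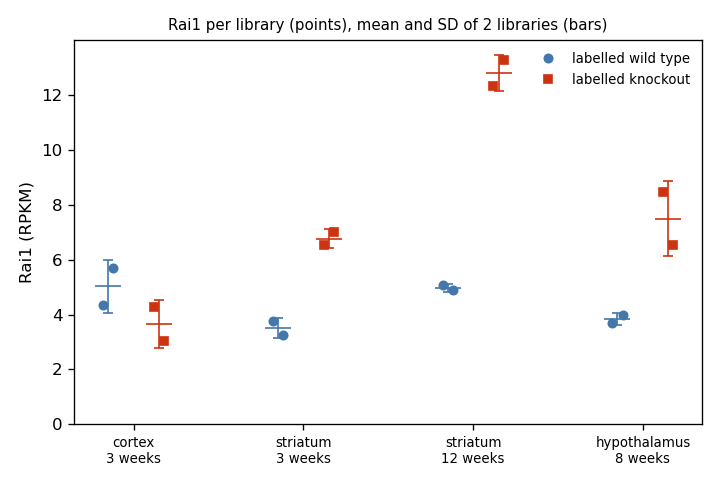
Rai1 in RPKM (vertical axis) in the 4 region and age sets (horizontal axis), with each library as a point and the mean and SD of 2 libraries as bars, for libraries labelled wild type and knockout. In striatum at 12 weeks the libraries labelled knockout sit at 12.3 and 13.3 RPKM, above the wild-type libraries at 5.08 and 4.88.

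The cortex comparison asked what deletion with Nestin-Cre, active in neural progenitors, changes by 3 weeks. In the libraries labelled knockout, 2 genes were higher and 3 were lower. Tex14, a gene for a protein of germ cell bridges, fell from 2.10 ± 0.225 to 0.0661 ± 0.00463 RPKM (log2 change -2.19, SE 0.12, adjusted p = 1.06e-06). A230057D06Rik rose from 0.774 ± 0.0438 to 3.50 ± 0.301 (adjusted p = 0.000122), and the non-coding RNA Ipw rose from 80.6 ± 6.17 to 198 ± 16.4 (adjusted p = 0.0193). Both belong to the imprinted Prader-Willi region, where Mkrn3 was at 0.565 and 1.49 without passing (adjusted p = 0.0965). Snrpn, of the same region, was at 0.31 and 0.35 in wild-type libraries and at 0.25 and 0.15 in knockout libraries. It stayed below the filter and was not tested. Glra3, a glycine receptor subunit, fell from 1.95 ± 0.215 to 0.802 ± 0.0373 (adjusted p = 0.0253). Among genes that did not pass, Gsn was at 8.03 and 19.3, Rras2 at 1.84 and 3.31, Alcam at 18.5 and 9.62 and Lyrm7 at 1.95 and 0.614 RPKM.

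Of the lists in cortex, 22 oligodendrocyte and myelin genes had 0 calls over all genes and 10 higher when adjusted over the list alone, with a median log2 change of 0.46. Ugt8a, an enzyme of myelin lipid synthesis, was at 17.6 ± 0.36 and 30.4 ± 2.69 RPKM, and Mog at 8.14 ± 0.339 and 14.1 ± 2.63. The list was past the camera threshold (adjusted p = 5.55e-16) but not with an estimated correlation (adjusted p = 0.239). The 14 oligodendrocyte precursor genes had 4 higher adjusted over the list alone, among them Gpr17 at 16.8 and 31.6, with camera adjusted p = 2.36e-12 and adjusted p = 0.239 with an estimated correlation. Of 32 cadherins and protocadherins, cell adhesion molecules, 6 were lower adjusted over the list alone and 0 over all genes (camera adjusted p = 1.69e-06, and adjusted p = 0.239 with an estimated correlation). Cdh8 was at 7.29 and 4.13, and Cdh7 at 2.39 and 1.22. Other lists also moved up in cortex by camera alone, and 4 of them are given here. Positive estimates were found for 63 of 74 oxidative phosphorylation genes (camera adjusted p = 0.000389), 18 of 21 heat shock and stress genes (0.00442), 12 of 15 endothelial (4.37e-05) and 15 of 18 astrocyte markers (0.00505). With an estimated correlation their adjusted p-values were 0.78, 0.78, 0.413 and 0.572. Spiny projection neuron markers had negative estimates for 19 of 20 genes, and meningeal and fibroblast markers had 3 of 10 higher adjusted over the list alone, with camera adjusted p-values of 7.83e-07 and 1.27e-05 that became 0.543 and 0.413 with an estimated correlation. The knockout replicates correlated at r of 0.971 and the wild-type replicates at 0.988. The count of 5 genes was 2 without wild-type replicate 1, wild-type replicate 2 or knockout replicate 1, and 8 without knockout replicate 2. It was 37 after median-ratio scaling and 0 when only the cortex libraries were fitted.

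The striatum comparison at 3 weeks asked what deletion with Gad2-Cre, active in GABAergic neurons, changes in juvenile mice. In the libraries labelled knockout, 4 genes were lower and 0 higher. The count of genes at an unadjusted p under 0.05 was 932, of which 298 were higher. Nts, the neuropeptide neurotensin, fell from 6.99 ± 1.64 to 1.03 ± 0.799 RPKM (log2 change -2.38, SE 0.32). Htr2a, a serotonin receptor, fell from 9.20 ± 2.79 to 3.38 ± 0.272 (-1.29, SE 0.17). Brinp3 fell from 4.52 ± 0.544 to 1.89 ± 0.0523 (-1.07, SE 0.13), and Pcdh20, a protocadherin, from 2.75 ± 0.181 to 1.16 ± 0.0968 (-0.97, SE 0.13). All 4 had an adjusted p of 0.0117. Fstl5 was at 2.58 and 1.11 (adjusted p = 0.054) and Cdh9 at 5.33 and 2.17 (adjusted p = 0.0557), and neither passed. On the other side, Fam163b was at 2.50 and 4.33, Rraga at 2.01 and 3.27, Itgbl1 at 0.622 and 1.24 and Samd5 at 4.42 and 6.52, all without passing.

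The median log2 change of all genes in this set was -0.13, and median-ratio scaling gave 5 lower genes, 3 of them among the 4, with Pcdh20 at an adjusted p of 0.0875. All 18 microglia markers had negative estimates and 7 were lower adjusted over the list alone, P2ry13 at 8.12 and 5.06 among them (camera adjusted p = 2.27e-07, and adjusted p = 0.783 with an estimated correlation). All 74 ribosomal protein genes had negative estimates, with a median of -0.34 (camera adjusted p = 0.000111, and adjusted p = 0.936 with an estimated correlation), as had 70 of 74 oxidative phosphorylation genes (0.00614 and 0.936). Potassium channel and synaptic vesicle genes were past the camera threshold upward (adjusted p of 1.81e-06 and 1.09e-06, and 0.595 and 0.783 with an estimated correlation). Cortical excitatory neuron markers had 5 of 19 higher adjusted over the list alone (camera adjusted p = 3.53e-06, and adjusted p = 0.595 with an estimated correlation). Among these, Slc17a7, the cortical vesicular glutamate transporter, was at 1.36 and 4.85 RPKM in wild-type libraries and 12.0 and 7.13 in knockout libraries, against 113 to 129 in cortex. The count of 4 was 1 without wild-type replicate 1, 0 without wild-type replicate 2, 2 without knockout replicate 1, none of them among the 4, and 1 without knockout replicate 2. It was 0 when only these 4 libraries were fitted.

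At 12 weeks the striatum comparison asked the same question in adult mice, and 1 gene was higher and 4 were lower in the libraries labelled knockout. The higher gene was Rai1. Htr2a fell from 4.94 ± 0.618 to 1.07 ± 0.0803 RPKM (log2 change -1.79, SE 0.17, adjusted p = 0.000835). Sema3a, a secreted axon guidance cue, fell from 1.81 ± 0.102 to 0.554 ± 0.0324 (-1.13, SE 0.13, adjusted p = 0.00259). Cdh9, a classical cadherin, fell from 8.82 ± 2.30 to 3.28 ± 0.156 (-1.28, SE 0.18, adjusted p = 0.0253), and Slitrk1, a synaptic adhesion protein, from 4.20 ± 0.640 to 1.98 ± 0.140 (-0.92, SE 0.14, adjusted p = 0.0347). Sema3e was at 3.75 and 1.65 without passing (adjusted p = 0.0547). Ttr, a choroid plexus transcript, was at 1.05 and 3.02, Otof at 0.864 and 1.8 and Nt5c1a at 0.652 and 1.65, and none passed.

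Of the 32 cadherins and protocadherins, 12 were lower and 1 higher adjusted over the list alone and 1 was lower over all genes. The list was past the camera threshold (adjusted p = 3.9e-17), and also with an estimated correlation (adjusted p = 0.0177), but missed it with fry (adjusted p = 0.0537). Pcdh20 was at 1.36 and 0.7, Cdh6 at 1.56 and 0.883 and Pcdh10 at 12.1 and 8.43. No other list in the 4 sets kept its camera call with an estimated correlation. Synaptic adhesion molecules had 4 of 57 lower adjusted over the list alone (camera adjusted p = 8.91e-11, and adjusted p = 0.463 with an estimated correlation). Cortical excitatory neuron markers had 6 of 19 lower adjusted over the list alone (adjusted p = 0.362 with an estimated correlation), with Slc17a7 at 2.68 and 9.58 in wild-type and 1.49 and 1.36 in knockout libraries. Ribosomal protein genes had positive estimates in all but 2 of 74, the opposite of 3 weeks (adjusted p = 0.828 with an estimated correlation). The median log2 change of all genes also differed, at 0.08 in this set and -0.13 at 3 weeks. For the tenth of genes with the shortest spans it was 0.1 and -0.19. Sign counts alone therefore cannot be told apart from a shift of whole libraries. Myelin genes had positive estimates in 21 of 22 and oxidative phosphorylation genes in 71 of 74 (camera adjusted p = 0.000205 for each, and 0.82 and 0.828 with an estimated correlation), as had 15 of 18 astrocyte markers (camera adjusted p = 0.0559). Axon guidance genes and monoamine and acetylcholine receptors were past the camera threshold downward (adjusted p of 1.61e-06 and 0.000205, and 0.643 and 0.745 with an estimated correlation). Htr2a passed under every alternative run for this set. The count of 5 was 7 without wild-type replicate 1, 2 without wild-type replicate 2 and 1 without either knockout replicate.

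The hypothalamus comparison asked what deletion with Vglut2-Cre, active in glutamatergic neurons, changes at 8 weeks. A single gene, the microRNA gene Mir6989, passed: it was at 2.13 and 1.32 RPKM in wild-type libraries and listed at 0 in both knockout libraries (adjusted p = 0.0359), and no library held more than about 3 reads of it. No gene was called higher, and 217 genes had an unadjusted p under 0.05 where chance gives 617. Replicates had a typical SD across genes of 0.15 and 0.16 on the log2 scale here, against 0.16 to 0.28 in the other sets. The fit shares a variance per gene over all sets, so p-values of a set with a smaller spread can be too large. More genes were called when only the hypothalamic libraries were fitted, as given below. Among genes that did not pass, Pcdh20 was at 8.70 ± 0.924 and 5.21 ± 0.618, Gabra2, a GABA receptor subunit, at 17.9 ± 1.6 and 10.2 ± 0.129, Pfdn4 at 2.10 and 0.968 and Sema3a at 0.961 and 0.358 RPKM. Nos1 was at 4.06 and 5.82 and Fstl4 at 1.16 and 1.86. Bdnf, a neurotrophin tied to feeding, was at 2.12 ± 0.243 and 1.27 ± 0.0280 (adjusted p = 1, and 0.0366 adjusted over the energy balance list alone). Npy, an appetite-stimulating peptide, was at 5.59 ± 1.16 and 2.97 ± 0.183, and Htr2c, a serotonin receptor, at 9.86 ± 0.231 and 5.88 ± 0.138. The list of 29 energy balance genes had 19 negative estimates, with 1 gene lower adjusted over the list alone, and did not pass (camera adjusted p = 0.0807), and 23 circadian clock genes had a median log2 change of -0.03 (camera adjusted p = 0.743). The myelin list had positive estimates in 21 of 22 genes (camera adjusted p = 1.76e-07, and adjusted p = 0.916 with an estimated correlation), and cadherins and protocadherins negative ones in 24 of 32 (3.05e-05 and 0.525). The call of Mir6989 was lost without any of the 4 libraries, with median-ratio scaling (adjusted p = 0.116) and with a pseudocount of 0.1 (adjusted p = 0.225).

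Averaged over the 4 comparisons, 44 genes were lower and 2 higher in the libraries labelled knockout. The lower genes with the largest mean changes were Nts (-1.13, SE 0.16, adjusted p = 0.0061), Htr2a (-1.01, SE 0.08, adjusted p = 9.06e-05), Cdh9 (-0.96, SE 0.09, adjusted p = 0.000244) and Sema3a (-0.81, SE 0.06, adjusted p = 6.27e-05). They were followed by Fstl5, Htr2c, Brinp3, Sema3e, Pcdh20 and Kctd8, with mean log2 changes of -0.72 to -0.61. Of the 44 genes, 43 had negative estimates in all 4 comparisons, and Tex14 in 3. The genes were called on the mean of these same estimates, so the agreement in sign is partly fixed by the choice. Shares in sets left out of the choice are given below. The mean of Tex14 rests on cortex. Without striatum at 3 weeks, where it was at -2.38, Nts had a mean of -0.71 and did not pass (adjusted p = 0.267). Sema3a was lower by 0.61 to 1.13 on the log2 scale in the 4 sets, at -0.61, -0.74, -1.13 and -0.77. The 2 higher genes were Rai1 (0.65, SE 0.09) and A230057D06Rik (0.57, SE 0.07). Without the cortex set, A230057D06Rik had an adjusted p of 0.999, and without striatum at 12 weeks Rai1 had 0.166.

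Cell adhesion genes made up the largest share of the lower genes that a list covered. Of 32 cadherins and protocadherins, 9 were lower over all genes, and 16 were lower and 1 higher adjusted over the list alone. Among them, Cdh7 had a mean log2 change of -0.48, Cdh10 of -0.45, Cdh8 of -0.41 and Pcdh10 of -0.39. The list was past the camera threshold (adjusted p = 2.79e-12) and past it with fry (adjusted p = 0.00164), and it missed it with an estimated correlation (adjusted p = 0.055). Of 57 synaptic adhesion molecules, 7 were lower over all genes (adjusted p = 0.783 with an estimated correlation). The 47 clustered protocadherins had 0 calls and a median of 0.00. Of 32 monoamine and acetylcholine receptors, 2 were lower, Htr2a and Htr2c (adjusted p = 0.783 with an estimated correlation). The 22 myelin genes had 0 calls and positive estimates in all but 1 (camera adjusted p = 2.08e-14, and adjusted p = 0.449 with an estimated correlation). At least 4 more cell-type lists had 0 calls over all genes and moved by camera alone. Spiny projection neuron markers had negative estimates in 16 of 20, 3 of them lower adjusted over the list alone, and microglia markers in 18 of 18 (camera adjusted p of 0.00055 and 0.0142). Precursor and meningeal markers had positive estimates in 11 of 14 and 8 of 10 (0.000164 and 1.37e-05). With an estimated correlation these 4 lists were at 0.783, 0.846, 0.783 and 0.591. Among choroid plexus markers, Ttr had a mean log2 change of 0.39, higher adjusted over the list alone (limma adjusted p = 0.011) but not over all genes. With 1 library left out, the count of 46 was 19 to 25 without any of the hypothalamic libraries, 21 and 29 without the wild-type cortex replicates 1 and 2, 22 and 25 without wild-type replicate 2 and knockout replicate 1 of striatum at 3 weeks, and 21, 24 and 22 without wild-type replicate 2, knockout replicate 1 and knockout replicate 2 of striatum at 12 weeks. Leaving out cortex gave 15 genes.

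**Figure D2:**
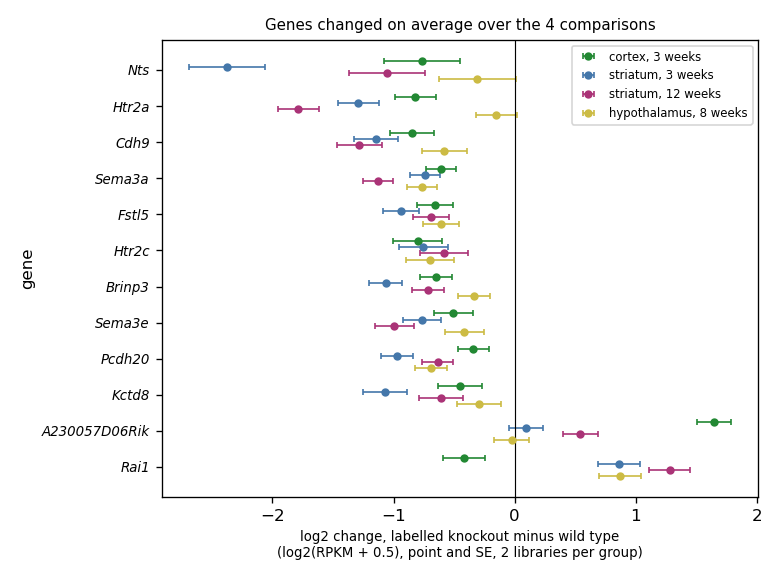
Log2 change of libraries labelled knockout minus wild type (horizontal axis, log2(RPKM + 0.5), point and SE, 2 libraries per group) in each of the 4 region and age sets for the 10 lower genes with the largest mean change and the 2 higher genes (vertical axis). Htr2a lies at -0.82, -1.29, -1.79 and -0.15, and Rai1 at -0.42 in cortex and 0.86 to 1.28 elsewhere.

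Overlap between the comparisons was tested per direction. At the adjusted threshold, Htr2a in both striatal sets was the only gene called in 2 sets. At an unadjusted p under 0.01, lower genes were shared more often than independent lists would give. The sets share a variance estimate per gene from the pooled fit, so a gene of low variance can pass in several sets. The lists are therefore not independent, and the expected counts and Fisher p-values cannot measure the excess. Overlap in opposite directions was not tested. After scaling, 13 of 30 genes at this threshold in both cortex and striatum at 3 weeks went opposite ways. Cortex shared 14 with striatum at 3 weeks against 1.05 expected, 18 with striatum at 12 weeks against 0.66, and 15 with hypothalamus against 0.46 (Fisher's exact adjusted p of 5.64e-12, 1.34e-20 and 8.88e-19). The striatal sets shared 14 against 0.46 expected, and hypothalamus shared 8 and 6 with them against 0.32 and 0.2. Higher genes shared 5 between the striatal sets against 0.32 expected, Rai1 among the genes higher in both, and 0 to 2 between other sets. Across all 12348 genes, the Spearman correlation of log2 changes was between -0.29 and 0.30 for the 6 pairs of sets. The lowest value was that of the striatal sets, which have the same region and Cre driver. The highest was that of striatum at 3 weeks with hypothalamus.

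The effect in cortex was compared with that in striatum at 3 weeks, which differ in Cre driver as well as region. A230057D06Rik differed by 1.56 on the log2 scale (SE 0.20, adjusted p = 0.0146), higher in cortex, and Tex14 by -2.18 (SE 0.17, adjusted p = 9.49e-05). In striatum at 3 weeks Tex14 was at 0.0190 and 0.0154 RPKM and A230057D06Rik at 2.79 and 3.01. Ipw differed by 1.49 (adjusted p = 0.162), Gsn by 1.61 (adjusted p = 0.168) and Rai1 by -1.28 (adjusted p = 0.286) without passing. The split of 1 higher and 1 lower became 2 higher and 1 lower after scaling, with Gsn at an adjusted p of 0.00715. Without cortex wild-type replicate 1, cortex wild-type replicate 2, cortex knockout replicate 1, striatum wild-type replicate 2 or striatum knockout replicate 2 the count was 1, and without cortex knockout replicate 2 it was 6. Between 12 and 3 weeks in striatum, the knockout effect differed for 0 genes with limma, with 1097 genes at an unadjusted p under 0.05, at a median difference of all genes of 0.20. The smallest p-values belonged to Ttr (1.76, adjusted p = 0.27) and Tbr1 (-1.94, adjusted p = 0.27), a cortical transcription factor, and Slc17a7 differed by -3.19 (adjusted p = 0.505). Without wild-type replicate 1 of 12 weeks, 11 genes were called.

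Wild-type striatum at 12 weeks was compared with that at 3 weeks. At 12 weeks 884 genes were higher and 3011 lower, and the median log2 change of all genes was -0.23. After median-ratio scaling 2300 were higher and 2092 lower. Oligodendrocyte genes were lower at 12 weeks: 21 of 22 myelin genes fell, with a median of -2.12, and none rose. Mog fell from 74.8 ± 8.99 to 8.06 ± 0.874 RPKM. Mal fell from 291 ± 20.5 to 35.3 ± 3.07, Cldn11 from 228 ± 36.8 to 28.7 ± 4.01 and Cnp from 360 ± 22.3 to 47.3 ± 3.89. Of 14 precursor genes 13 fell, Gpr17 from 40.9 ± 5.88 to 6.20 ± 1.24. Of 20 cholesterol synthesis genes 19 fell, with a median of -1.29, as did 13 of 18 astrocyte and 16 of 18 microglia markers. Lists kept as technical checks went down too: 32 of 74 oxidative phosphorylation genes fell and 1 rose, with a median of -0.68, as did 15 of 74 ribosomal protein genes with 1 higher, and 9 of 21 heat shock and stress genes with 1 higher. Among these, Rpl39 fell by 1.81 on the log2 scale, Ndufb9 by 1.30, Hspa5 by 1.63 and Tsc22d3 by 2.16, and 7 of 15 endothelial markers fell, Slc2a1 by 1.08. With an estimated correlation the adjusted p was 0.907 for oxidative phosphorylation, stress and endothelial genes, 0.908 for ribosomal proteins, 0.496 for myelin, precursor and cholesterol synthesis genes, 0.677 for astrocytes and 0.905 for microglia. With fry, myelin, precursor, cholesterol synthesis, astrocyte and microglia genes were at 1.3e-05, 7.63e-05, 0.000114, 0.000501 and 0.0108, and oxidative phosphorylation, ribosomal, stress and endothelial genes at 0.134, 0.482, 0.0993 and 0.0164. Myelin levels at 3 weeks in cortex, with Mog at 8.14 ± 0.339 RPKM, lay far below those in striatum of the same age. In wild-type hypothalamus at 8 weeks Mog was at 10.8 ± 0.0417. The wild-type striatal libraries of 3 weeks were also deeper, at 35635562 and 34378551 estimated reads against 21830346 and 22536005 at 12 weeks. For the 3895 genes called, age therefore cannot be told apart from other differences between these sets of libraries.

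Several of the genes with the largest rises at 12 weeks were under 0.2 times their lowest 12-week level in all striatal libraries at 3 weeks, labelled wild type or knockout. 4933409K07Rik was at 0.0534 ± 0.00579 at 3 weeks and 25 ± 1.67 at 12 weeks, and at 36.3 ± 2.04 in wild-type cortex at 3 weeks. Gm12070, a processed pseudogene, was at 3.33 ± 0.17, 88.9 ± 9.64 and 84.0 ± 11.5 in the same groups. Gm14440 was listed at 0 in both wild-type striatal libraries at 3 weeks and was at 6.85 ± 0.583 at 12 weeks. There were 35 genes whose highest level in striatum at 3 weeks was under 0.2 times their lowest level in striatum at 12 weeks, with at least 1 RPKM there, and 5 genes with the reverse. In 3-week cortex, which was not used to choose them, the 35 genes had a median of 3.05 RPKM, against 4.05 in striatum at 12 weeks. The count of 3895 was 1549 without 3-week replicate 2 and 1494 without 12-week replicate 1.

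**Figure D3:**
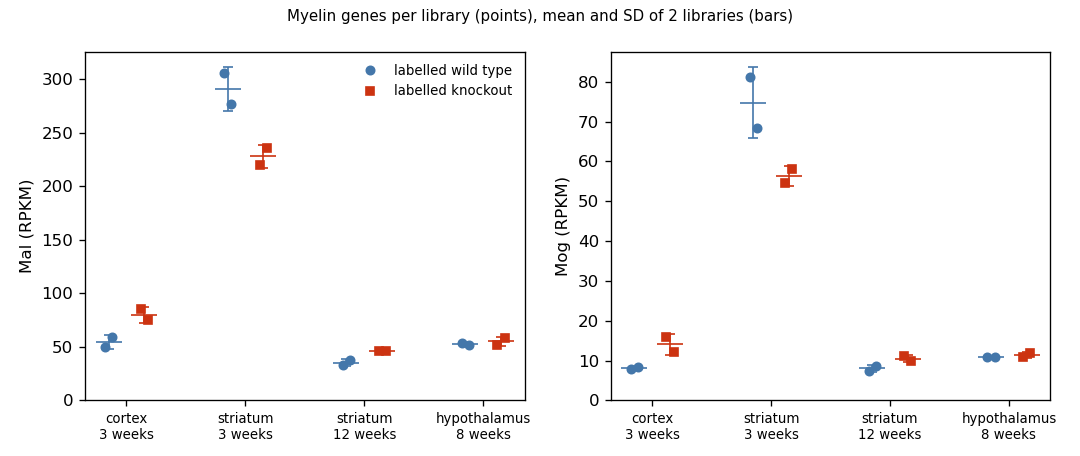
Mal and Mog in RPKM (vertical axes) in the 4 region and age sets (horizontal axes), with each library as a point and the mean and SD of 2 libraries as bars, for libraries labelled wild type and knockout. Mal lies at 306 and 277 RPKM in wild-type striatum at 3 weeks and at 33.2 and 37.5 at 12 weeks.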

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

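The tests of label exchange, of reads outside the deleted segment and of the surroundings of Tex14 were chosen only after the results were seen, and the difference between cortex and striatum was planned. Rai1 had a negative estimate in cortex, which did not pass the test, and positive estimates in the other 3 sets, called only in striatum at 12 weeks. Its level was lower in both cortex libraries labelled knockout than in both labelled wild type, and higher in both libraries labelled knockout of every other set. The difference of the log2 changes was 1.28 against striatum at 3 weeks, 1.70 against striatum at 12 weeks and 1.29 against hypothalamus. The first was tested and had an adjusted p of 0.286 over all genes, and the other differences were not tested. If the labels of 1 set alone had been exchanged, genes changed in the mean of the other 3 sets would go the other way in it. Of the genes called in that mean, Rai1 left out, 84.4% went the same way in striatum at 3 weeks (27 of 32, exact 95% interval 67.2% to 94.7%), 95.2% in striatum at 12 weeks (20 of 21, 76.2% to 99.9%), 94.4% in hypothalamus (34 of 36, 81.3% to 99.3%) and 92.9% in cortex (13 of 14, 66.1% to 99.8%). After scaling the shares were 75.5% (61.1% to 86.7%), 96.7%, 97.7% and 100%. This argues against an exchange in any single set, although genes are not independent and these intervals are too narrow. An earlier test, first pooled and then split by set, took genes at an unadjusted p under 0.01 in cortex and in the other set, after scaling. It gave 91.1% the same way for striatum at 12 weeks and 92.9% for hypothalamus, but 56.7% for striatum at 3 weeks (17 of 30, 37.4% to 74.5%), and 71% there with the gene length trend removed (22 of 31, 52% to 85.8%). Each change of this test was made after the earlier result had been seen. An exchange in all 4 sets stays open, since Rai1 in cortex, at -0.42 on the log2 scale, did not pass the test. Reads from the part of Rai1 outside the deleted segment, a candidate explanation for a higher total, cannot be separated with 1 value per gene. A true change of the Rai1 transcript was not tested and stays open as well.

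Tex14 and A230057D06Rik had knockout effects that differed between cortex and striatum at 3 weeks by -2.18 and 1.56 on the log2 scale. Tex14 in cortex rested on 274 and 330 approximate reads in wild-type libraries against 8 and 9 in knockout libraries. In hypothalamus it was at 3.05 ± 0.176 RPKM in wild-type and 2.96 ± 0.307 in knockout libraries, and in striatum at no more than 0.0202 in any group mean. Tex14 lies on the chromosome of Rai1 in the annotation used. Of 226 genes at an unadjusted p under 0.01 in cortex, 19 of the 966 tested genes on that chromosome were among them, against 17.7 expected. Of the 20 nearest tested genes, 1 had an unadjusted p under 0.01 in cortex, Sept4, with a log2 change of -0.74 (adjusted p = 0.121). Sept4 is the tested gene next to Tex14 on one side, and the gene after it, Mtmr4, was at -0.38 (unadjusted p = 0.0301). On the other side the next gene, Ppm1e, was at -0.02, and all remaining neighbours had an unadjusted p of 0.134 or more. These counts leave open an effect limited to the genes closest to Tex14.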

How the results depend on the processing

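Tests on a covariate for library medians, on the gene length trend, on approximate reads, on crossed pairs and on leaving out a comparison were chosen after the data were seen. Counts below are in the order cortex, striatum at 3 weeks, striatum at 12 weeks and hypothalamus where 4 are given. The counts were 5, 4, 5 and 1. With a threshold of 0.10, cortex and both striatal sets had 14, 9 and 8. A filter of 5 RPKM gave 2 in cortex, 7 in striatum at 3 weeks, 0 in hypothalamus, 27 for the mean, 1 for cortex against striatum and 2498 for wild-type age, with fewer genes tested. No filter gave 34 in cortex, 4 in hypothalamus, 2 for the striatal age difference and 10 for cortex against striatum, with 20473 genes tested. A pseudocount of 1 gave 8 in cortex, and one of 0.1 gave 0 in hypothalamus. Median-ratio scaling gave 37 in cortex, 9 in striatum at 12 weeks and 0 in hypothalamus, and quantile normalization 55, 9 and 0. Fitting only the groups compared gave 0, 0, 13 and 10, and 1 for cortex against striatum. Precision weights gave 8 in cortex and 9 in striatum at 3 weeks, and a minimum of 10 reads gave 3 in cortex and 0 in hypothalamus. A covariate for library medians gave 121, 9, 13 and 3, 92 for the mean, 2 for the striatal age difference and 23 for cortex against striatum, and kept all 46 genes of the mean. Removing the length trend gave 42, 10, 11 and 2, 74 for the mean and 3 for the striatal age difference. Leaving out cortex or striatum at 12 weeks gave 15 and 21 for the mean. For these moves in counts the cause was not tested.

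Replicate numbers are shared between groups, and the deviations of libraries of the same number correlated at -0.34, 0.44, -0.22 and 0.15 in the 4 sets. With signs that differ between sets, these values do not settle whether the numbers pair libraries. With a replicate block the counts were 3, 1, 1 and 0, with 12 for the mean and 1 for cortex against striatum. Crossed pairs in cortex and striatum at 12 weeks, chosen for their negative correlation, gave 42 in cortex, 30 in striatum at 3 weeks, 0 in hypothalamus, 94 for the mean, 14 for cortex against striatum and 6165 for wild-type age.

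With 1 library left out, the lone library being assumed to vary like the others, counts were 2 to 8 in cortex, 0 to 2 in striatum at 3 weeks, 1 to 7 in striatum at 12 weeks and 0 to 1 in hypothalamus. They were 19 to 55 for the mean, 0 to 11 for the striatal age difference, 1 to 6 for cortex against striatum and 1494 to 4287 for wild-type age. No named gene called in the main analysis turned its sign. Genes at the mean level such as Htr2a, Cdh9, Sema3a and Fstl5 passed in every alternative run. With 2 libraries per group and simulated noise independent between genes, a change of 0.5 on the log2 scale was recovered in 0.2% of genes in cortex. The other single sets were not simulated.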

Other observations

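The tests of cortical tissue, of the gene length trend, of pseudogenes and of age were chosen only after the result was seen, as was the covariate for library medians. The 21 immediate early genes, which follow neuronal activity, had a median log2 change between -0.16 and 0.14 in the 4 sets, with no list call that held with an estimated correlation. Nr4a2, a member, was at 0.261 ± 0.073 and 1.55 ± 0.304 RPKM in striatum at 3 weeks and at 1.37 ± 1.18 and 0.216 ± 0.216 at 12 weeks, in step with Slc17a7, and neither difference passed over all genes. Adjusted over the list alone, Nr4a2 was higher (log2 change 1.43) and Npas4 lower (-0.75) in striatum at 3 weeks (both adjusted p = 0.0119), and Bdnf lower in hypothalamus (-0.56, adjusted p = 0.0265). Penk, an opioid peptide precursor, was at 24.3 ± 3.51 and 13.7 ± 5.03 in cortex, without passing. Hcrt was listed at 0 in both wild-type cortex libraries and had a mean of 0.465 ± 0.327 in those labelled knockout (log2 change 0.91, adjusted p = 0.158, and 0.0133 over the energy balance list alone). That mean lies below the filter level of 1 RPKM, so the list call of Hcrt rests on low values. A hypothesis set down beforehand, that genes with long transcribed spans are lower in the libraries labelled knockout, was not borne out. Spearman rho across genes of the mean log2 change with the span was 0.08, and it was -0.18 in cortex, 0.29 and -0.09 in striatum at 3 and 12 weeks and 0.11 in hypothalamus.

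The 44 genes lower on average over the 4 sets were weighed against technical explanations. Of 100 splits of the 16 libraries within region and age, the real one included, 2 called as many as 46 genes. That share is within the limit set beforehand, but it does not exclude a random grouping. The reason is that another split, which mixed the labels in 3 of the 4 sets, called far more genes. In hypothalamus that split was the same as wild type against knockout, so it was not fully unrelated to the labels. This other split called 2846 genes, and no further split called more than 4. It separates the libraries of lower from those of higher median in 3 of the 4 sets, which points to a structure of the samples: the first axis of variation within sets held 45.9% of the variance, and library medians ranged from -0.18 to 0.13 on the log2 scale around their set. With that median as a covariate 92 genes were called, all 46 among them. A different share of cortical tissue would move these genes with Slc17a7, which after scaling was 1.78 higher in striatum at 3 weeks and changed by -1.67 at 12 weeks. Of the 28 genes called lower in the mean of the other 3 sets, chosen without striatum at 3 weeks, 24 were lower there as well (85.7%, exact 95% interval 67.3% to 96%, too narrow since genes are not independent). A gene length trend was removed from each library, and 41 of the 44 genes were still called, with a median change of -0.46 against -0.47, so these tests argue against both as the whole cause.

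The 35 genes under 0.2 times their lowest 12-week level in all striatal libraries at 3 weeks were weighed next. They were chosen from striatum alone, after an earlier choice that had used every library was dropped. An age effect alike in both regions would leave them low in 3-week cortex too. There they had a median of 3.05 RPKM, against 4.05 in striatum at 12 weeks and 0.0968 in striatum at 3 weeks, which argues against such an effect. An age effect in striatum alone stays open and was not tested. Pseudogenes made up 46.4% of the 28 genes with an annotated type, against 0.675% of all tested genes with one (Fisher's exact p = 7.54e-22). This is consistent with reads that match several places having been handled differently in those 4 libraries, as a hypothesis. Genes under 0.2 times their lowest level in all other libraries numbered 27 for striatum at 3 weeks, 1 each for cortex and striatum at 12 weeks, and 29 for hypothalamus.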
